A study of Corbicula fluminea with 24 samples.

How the data were processed

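RNA-seq libraries came from the digestive gland of 24 Corbicula fluminea caged at 3 sites, with 8 individuals per site and 1 library per individual. Per the labels' protocols, total RNA was isolated with a Promega SV kit and libraries were made with the TruSeq RNA v2 kit. The deposited table holds 1 count column per library, which are raw read counts per assembled contig; they are whole numbers whose totals differ between libraries. BWA 0.7.12 and SAMtools 1.1 are named in the submitters' processing notes. The assembly, the counting rule, the way contigs were named and any filter applied before deposit are not given in the sources used here. No column was left out. Site came from the labels and the sequencing lane from the column descriptions; lane 3 and lane 4 hold 4 libraries of each site.

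Contigs with low counts were removed with edgeR's filterByExpr by site (minimum count 10), which left 57593 of 58291 contigs; the 698 removed held 0.00718% of counts. Libraries were scaled with TMM factors. The 24 libraries were fitted together with edgeR 4.0.16 (robust quasi-likelihood) in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Log2 fold changes are first site over second, errors are standard errors of the log2 fold change, and CPM values use the TMM-scaled library sizes. Library totals had a median of 61.1 M. A contig with 0 counts in a library may have up to 3 expected counts at 95% confidence, which is 0.0792 CPM at the smallest scaled library size and 0.0323 CPM at the largest. The biological coefficient of variation was 45.8%. On simulated counts for the same 57593 contigs, the test recovered 13.4% of 1.5-fold, 46.3% of 2-fold and 68.2% of 4-fold changes in WWTP against reference (5.56% of calls false), 10.4%, 50.7% and 75.8% in urban runoff against reference (6.19% false), and 11.9%, 41.8% and 87.9% in WWTP against urban runoff (3.09% false). The simulated contigs varied independently of each other, while many real ones vary together, so these rates may not carry over to the real libraries.

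The rule for naming genes was fixed before the table was opened. In each comparison it takes, among contigs with adjusted p under 0.05, a mean of at least 2 CPM and medians that differ in the direction of the fold change, the 8 with a symbol and the largest log2 fold change in each direction, and list members past the threshold up to 4 per list. For contigs without a symbol it takes 2 that rose and 2 that fell, with a mean of at least 5 CPM and no overlap between the 8 values of each site. Of 22 lists of name patterns fixed before the table was opened, 4 had at least 5 measured members; 21 further lists were drawn up from the symbols after the names were seen and before any test, of which 19 had at least 5. These 23 lists were tested with camera (limma 3.58.1, preset correlation 0.01 and estimated correlation) and with fry, and adjusted over 69 tests.

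Separation of sites was tested by pseudo-F on Euclidean distances of log2 CPM (prior count 2), with all 12870 splits for a pair of sites and 1e+05 permutations for the 3 sites. Library measures, distances to the site centre and component positions were tested by two-sided exact permutation, and within a lane by all 70 splits. The relation of library totals to the first principal component was tested by permutation. Overlap of calls was set beside simulated unchanged groups against the same reference libraries and beside parts of 4 reference libraries. Alternatives tried were other scalings, other filters, lane as a term, single lanes, fits of 2 sites, a threshold of 0.01, glmTreat, DESeq2 1.42.0, limma-voom with sample weights, and each library left out in turn. A term for the first principal component, a term for the mean of 6 digestive hydrolases that follow it, and the exclusion of 6 libraries were chosen after seeing the data. The highest correlation between 2 libraries was 0.9767, and no library was a copy of another. No paired analysis was possible because replicate numbers are in accession order and mark no shared animal. Figures were drawn with python 3.11.15.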

Results

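The data describe the digestive gland of the Asian clam Corbicula fluminea, a freshwater bivalve that feeds by filtering particles from the water. In bivalves this gland takes up and digests food and is a main site of lipid storage and of the handling of foreign compounds. Clams were caged from December to March at 3 sites, namely a reference site, a site downstream of a wastewater treatment plant (WWTP) and a site downstream of an urban runoff effluent. RNA of 8 individuals per site was sequenced, 1 library per clam, so that p-values measure the spread between animals of 1 caging per site, and site cannot be told apart from cage. Within each site 4 libraries came from lane 3 and 4 from lane 4. Total counts per library ranged from 40.4 M to 97.7 M. Means were 71.0 M ± 8.06 (SD, n = 8) at the reference site, 60.4 M ± 12.7 at the WWTP site and 62.9 M ± 17.5 at the runoff site. The table covered 58291 contigs, of which 1603 carried a gene symbol, 19389 a locus number or tag and 37299 only a contig number. Names below are those of the table, which pairs no description, source species or coordinates with them, so symbols are described by what the gene of that name is known to do in other animals. An ending such as 2.2 marks 1 of several contigs with the same name, between which reads may be split, and their values are uncertain to that extent.

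Several digestive enzyme transcripts varied widely between clams. The genes in this paragraph were chosen after their values were seen. GUN, an endoglucanase that breaks down cellulose, ranged from 2.74 CPM (counts relative to the scaled library size) in runoff individual 56 to 1077 CPM in WWTP individual 46. Amy.1.2, an amylase, spanned 3.33 to 831.6 CPM in the same clams, the lipase LIPA 0.839 to 181.6 CPM, the lysozyme LYS3.4.4 5.43 to 2340 CPM and the defensin BDEF.1.2 1.17 to 568.1 CPM. Transcripts that ran the other way include the muscle myosin MYS.1.2 (40.4 to 4702 CPM) and the egg yolk precursor Vg.1.2 (45.3 to 6326 CPM). The first principal component of the libraries, called the digestive component below, held 58.8% of the variance, and 3949 contigs fell along it with a correlation below -0.9. Digestive enzymes did not all follow it. Of 20 digestive and lysosomal hydrolases on the list used below, 6 had a correlation below -0.9 and 3 above 0.5, and 11 increased along the component. The chymotrypsin-like ctrl.L (2.69 to 577.4 CPM) and, outside the list, the tryptase TRYM (1.59 to 286.6 CPM) ran against GUN and Amy.1.2.

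**Figure D1:**
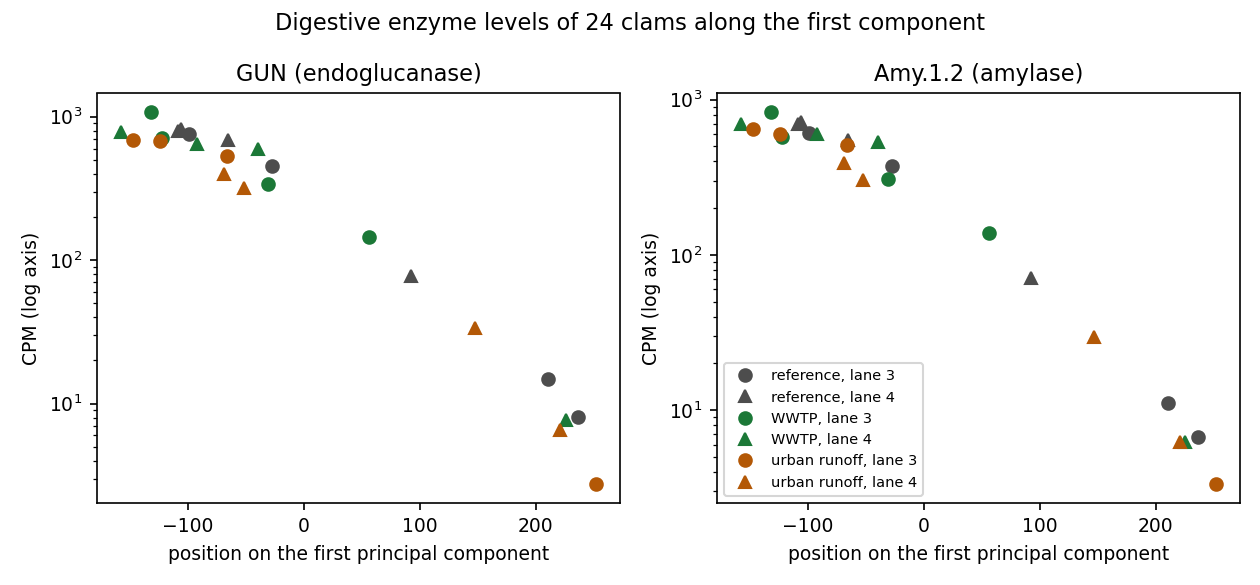
GUN and Amy.1.2 in CPM (log axis) of each of the 24 clams against the position of its library on the first principal component, coloured by site, with circles for lane 3 and triangles for lane 4. GUN spans 2.74 to 1077 CPM and Amy.1.2 3.33 to 831.6 CPM, and libraries of each site lie at both ends.

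Position on the digestive component did not differ between sites beyond the spread between clams, by two-sided exact permutation tests (n = 8 per site; WWTP against reference p = 0.438, urban runoff against reference p = 0.954, WWTP against urban runoff p = 0.44). Within lane 3 the exact p were 0.2, 0.371 and 0.857, and within lane 4 they were 0.743, 0.2 and 0.514. Over all contigs the sites did not separate either. The ratio of between-site to within-site distance (pseudo-F) was 1.11 for WWTP against reference (exact permutation p = 0.287), 0.511 for urban runoff against reference (exact p = 0.664) and 1.01 for WWTP against urban runoff (exact p = 0.335). Site held 7.63% of the variance among the 3 sites (permutation p = 0.479). Within lane 3 the exact p for these pairs were 0.2, 0.286 and 0.714, and within lane 4 they were 0.629, 0.171 and 0.486. The mean distance of a clam to its site's centre was 155 ± 54.3 (SD, n = 8) for WWTP, 178 ± 43.3 for runoff and 165 ± 43.6 for reference libraries, in log2 CPM units. The exact permutation p were 0.709, 0.558 and 0.373 for the pairs in the order above.

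The comparison of WWTP with reference clams addresses how the digestive gland transcriptome differs below a treated wastewater outlet. SAA2.2.2, a serum amyloid A, named for acute-phase proteins of vertebrates, stood at 9.57 ± 7.20 CPM (SD, n = 8) in WWTP clams and 1.58 ± 1.33 CPM in reference clams, a rise of 6.05-fold (log2 fold change 2.6, SE 0.589; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0294). With the digestive component as a term, chosen after seeing the data, its log2 fold change was 1.96 (SE 0.549, edgeR adjusted p = 0.0436). ifi44_bis, named for an interferon-induced protein, rose from 1.40 ± 0.579 to 4.11 ± 2.52 CPM (log2 fold change 1.55, SE 0.35, edgeR adjusted p = 0.0291). mgst1.1.2, a microsomal glutathione S-transferase that conjugates lipophilic compounds, rose from 20.8 ± 3.03 to 31.1 ± 7.57 CPM (log2 fold change 0.58, SE 0.14, edgeR adjusted p = 0.0358). The other contig of this name, mgst1.2.2, stood at 143 ± 84 against 79.4 ± 58.8 CPM. It missed the threshold (log2 fold change 0.85, SE 0.628, edgeR adjusted p = 0.609). sec61g, a subunit of the channel that passes proteins into the endoplasmic reticulum, rose from 72.2 ± 18.0 to 122 ± 29.5 CPM (log2 fold change 0.76, SE 0.174, edgeR adjusted p = 0.0304). FBCD1.2.6, a fibrinogen-domain receptor that binds acetylated sugars, fell from 8.88 ± 1.1 to 6.86 ± 0.746 CPM (log2 fold change -0.37, SE 0.0886, edgeR adjusted p = 0.0347).

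**Figure D2:**
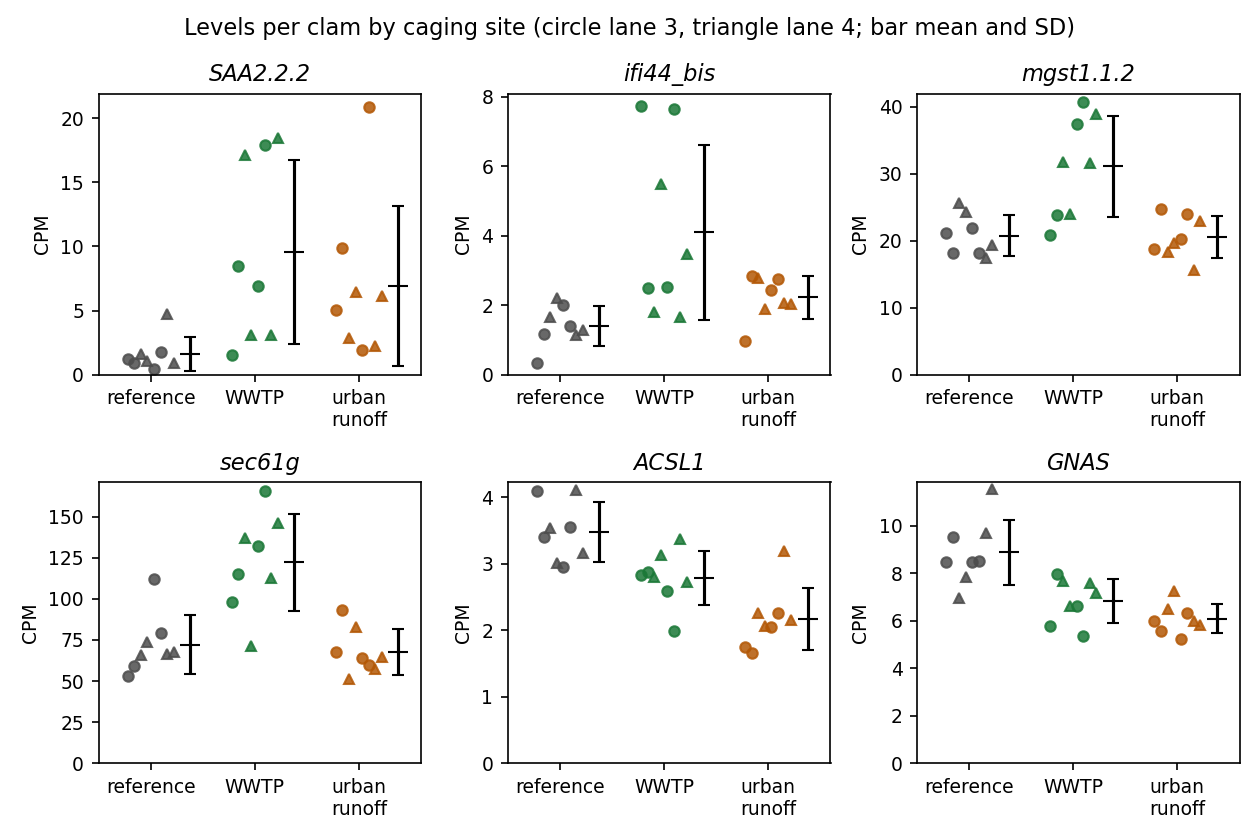
CPM of 6 named genes in each clam, by site (8 clams per site; circles lane 3, triangles lane 4), with the mean and SD beside each group. SAA2.2.2 averages 9.57 CPM at the WWTP, 6.93 CPM at the runoff and 1.58 CPM at the reference site, while ACSL1 averages 2.17 CPM in runoff and 3.47 CPM in reference clams.

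Other symbols that rose in WWTP clams were NUCL, nucleolin (log2 fold change 0.57, SE 0.112, edgeR adjusted p = 0.0174), GAR1, a subunit of the particle that guides pseudouridylation of ribosomal RNA (0.56), and HNRL1, a heterogeneous ribonucleoprotein of the U type (0.68). Safb, a scaffold attachment factor, rose too (0.55, SE 0.113, edgeR adjusted p = 0.0204). Symbols that fell were RNF34, a ubiquitin ligase (log2 fold change -0.52), Macoilin, a membrane protein of the endoplasmic reticulum (-0.52), higd2a, which takes part in assembly of the respiratory chain (-0.49, SE 0.103, edgeR adjusted p = 0.0213), and Bscl2, seipin, which shapes lipid droplets (-0.44). RNF34 (-0.43), higd2a (-0.46) and Bscl2 (-0.43) were also lower in runoff than in reference clams with the digestive component as a term. That term was chosen after seeing the data. The edgeR adjusted p there was 0.0366, 0.021 and 0.0499, and Macoilin was not called. Without the term none of them passed in runoff clams. Chosen after their values were seen, since they lie outside the naming rule, METK2, which makes S-adenosylmethionine, stood at 1.24 CPM in WWTP against 0.663 CPM in reference clams (log2 fold change 0.90, edgeR adjusted p = 0.00834). Chosen in the same way, the oligosaccharyltransferase subunit OST4 stood at 73.9 against 51.2 CPM (0.53) and WSCD2 at 1.62 ± 1.2 against 0.104 ± 0.0971 CPM (3.9, SE 0.612, edgeR adjusted p = 0.00396). The reference mean of WSCD2 lies near the 0.0792 CPM that 0 counts allow in the smallest library, so the size of its change is uncertain. Without a symbol, contig_33140 rose from 1.27 ± 0.875 to 25.5 ± 24.5 CPM (log2 fold change 4.33, SE 0.706, edgeR adjusted p = 0.00533) and LOC108269088.3.3 from 3.10 ± 2.94 to 35.0 ± 30.4 CPM (3.50, SE 0.673). LOC108269088.3.3 follows contig_27540, described below, across libraries (r = 0.906), with contigs of unknown source, so it is not a finding separate from that contig. Both contig_33140 and LOC108269088.3.3 were highest in WWTP individual 37 (69.6 and 92.1 CPM), and whether they vary together was not tested. Also without a symbol, LOC101857055 (-1.56) and LOC105340963.2.2 (-1.45) fell. All 8 WWTP libraries lay beyond the reference median for each gene named by the rule here. For contigs without a symbol the rule asks for no overlap, which fixes this in advance. For symbols chosen by fold change it asks for medians in that direction, which favours it.

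In all, 846 of the 57593 contigs tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 584 higher and 262 lower in WWTP clams, with 124 beyond 2-fold. Of the symbols, 17 were higher and 6 lower. Scaling by library totals alone called 165 contigs, 38 higher and 127 lower, and moved the median log2 fold change of all contigs from 0.00645 to -0.16. With it SAA2.2.2 (edgeR adjusted p = 0.0666), ifi44_bis (0.0608), mgst1.1.2 (0.0856) and sec61g (0.0639) missed the threshold. So did NUCL (edgeR adjusted p = 0.136), Safb (0.118), HNRL1 (0.154), GAR1 (0.169), RNF34 (0.0613), Macoilin (0.0818), higd2a (0.0585), FBCD1.2.6 (0.0934) and LOC105340963.2.2 (0.0532). No contig passed within lane 3 alone (edgeR, 3975 at an unadjusted p under 0.05) and 1 within lane 4 (6261), where no other tool was run. None passed a test against a log2 fold change beyond 1 (edgeR glmTreat, 218 at an unadjusted p under 0.05), while DESeq2 called 2328 and limma-voom 2606 contigs. A fit of these 2 sites alone called 516, upper-quartile scaling 522, and, chosen after seeing the data, the component as a term 2649 and the exclusion of the 6 libraries lowest in digestive hydrolases 268. The count was 206, 334, 365 and 500 without WWTP individuals 46, 42, 38 and 48. It was 218, 263, 394, 414, 460, 499 and 520 without reference individuals 31, 30, 22, 23, 20, 21 and 29. It was 1342 and 1297 without reference individual 25 and runoff individual 49. NUCL, Safb, contig_33140 and LOC108269088.3.3 passed with any single library left out. Of the others SAA2.2.2 rose to an edgeR adjusted p of 0.0735, ifi44_bis to 0.0788, mgst1.1.2 to 0.0931, sec61g to 0.074, FBCD1.2.6 to 0.0919 and Bscl2 to 0.108, each without WWTP individual 46. Without the same clam it was 0.104 for HNRL1, 0.0792 for GAR1, 0.0664 for RNF34, 0.0935 for Macoilin and 0.0664 for LOC105340963.2.2. It was 0.0556 for higd2a without reference individual 31 and 0.0743 for LOC101857055 without reference individual 21.

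Gene lists were drawn up from the symbols in the table, after the names were seen and before any test, and compared with all other contigs by camera, with adjustment over 23 lists in 3 comparisons. Genes of phase I and II metabolism of foreign compounds were higher in WWTP clams as a group (27 members, median log2 fold change 0.43, 81.5% positive; camera adjusted p = 0.00157, and adjusted p = 0.368 with an estimated correlation). Of its members 1 rose, mgst1.1.2, and 3 passed when adjusted over the list alone. The other 2 were ADHX.2.2 (2.04, adjusted p = 0.0299 over the list) and ADHX.1.2 (1.90, adjusted p = 0.0347), class III alcohol dehydrogenases that clear formaldehyde bound to glutathione. Both follow contig_27540 across libraries (r above 0.9), with contigs of unknown source. Along the digestive component the list goes both ways, with a correlation below -0.9 in 6 members and above 0.5 in 7, and with the component as a term, chosen after seeing the data, its camera adjusted p was 0.000125 (adjusted p = 0.418 with an estimated correlation). Ribosomal proteins and translation factors were higher by a small amount (34 members, median 0.21, 94.1% positive; camera adjusted p = 0.000226, and adjusted p = 0.963 with an estimated correlation). No member passed in edgeR or DESeq2 and 1 did in limma-voom, with 10 above and 0 below at an unadjusted p under 0.05. The estimated correlation between members was 0.788, against the preset 0.01. Contigs above 100 CPM rose as a class in this comparison, with medians of 0.209 for symbols (80.6% positive), 0.252 for locus-named and 0.203 for number-only contigs. Whether the list differs from contigs of like abundance was not tested. The list of ribosomal protein names fixed before the data were examined gave camera adjusted p = 0.00422 (12 members, median 0.31; adjusted p = 0.963 with an estimated correlation). Of these, 0 passed in edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05.

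Other lists gave no call as groups in WWTP clams. Of 93 genes of immune recognition and effectors, SAA2.2.2 rose, FBCD1.2.6 fell, and the C-type lectin CLC4M.3.3 (log2 fold change -1, edgeR adjusted p = 0.143) and the tachylectin TL5B.2.2 (-1.05, edgeR adjusted p = 0.122) missed the threshold (camera adjusted p = 0.509). In this list DESeq2 called 1 higher and 2 lower and limma-voom 1 higher and 4 lower. At an unadjusted p under 0.05 in edgeR 1 was higher and 9 lower. Of 52 interferon-type and antiviral genes ifi44_bis rose in edgeR and DESeq2 but not in limma-voom (camera adjusted p = 0.723). Of 18 heat shock proteins and folding helpers none passed over all contigs, 2 did in DESeq2 and 2 in limma-voom. Adjusted over the list alone 3 passed, the cyclophilin ppia (0.88) and the FK506-binding proteins FKB1A (0.35) and FKBP8 (0.59), with a camera adjusted p of 0.282. Camera adjusted p was 0.385 for redox defence, 0.723 for metal and iron handling, 0.954 for apoptosis, 0.723 for digestive and lysosomal hydrolases, and 0.685 for mitochondrial genome transcripts. It was 0.146 for nuclear respiratory chain genes, 0.253 for central energy metabolism, 0.346 for lipid and sterol metabolism, 0.723 for cell division, 0.94 for DNA damage response and 0.992 for mobile elements. Among markers of other tissues, the median log2 fold change was 0.39 for muscle (camera adjusted p = 0.482), 0.13 for cilia and tubulin (0.974) and 0.08 for the germline (0.977).

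The comparison of urban runoff with reference clams addresses how the gland differs below a stormwater outlet. ACSL1, which activates long-chain fatty acids, fell from 3.47 ± 0.446 to 2.17 ± 0.466 CPM (SD, n = 8; log2 fold change -0.68, SE 0.122, edgeR adjusted p = 0.0362). GNAS, the stimulatory G protein alpha subunit that couples receptors to cyclic AMP, fell from 8.88 ± 1.38 to 6.08 ± 0.617 CPM (-0.55, SE 0.101, edgeR adjusted p = 0.0362). With the digestive component as a term, chosen after seeing the data, GNAS was also lower in WWTP than in reference clams. Its log2 fold change there was -0.38 (SE 0.102, edgeR adjusted p = 0.0366). In the fit without that term no symbol rose in runoff clams (edgeR). Without a symbol, contig_27540 rose from 87.3 ± 63.4 to 1145 ± 1032 CPM (log2 fold change 3.71, SE 0.649, edgeR adjusted p = 0.0351) and contig_19638 from 29.3 ± 19.2 to 378 ± 336 CPM (3.69, SE 0.641). These contigs follow each other across libraries (r = 0.996), so their rises are 1 result. By contrast, LOC106051311 (-0.68, SE 0.0986, edgeR adjusted p = 0.0136) and LOC105346775.3.3 (-0.66) fell. All 8 runoff libraries lay beyond the reference median for each of these. For the contigs without a symbol the rule, which asks for no overlap, fixes this in advance. SAA2.2.2 stood at 6.93 CPM in runoff clams against 1.58 CPM (log2 fold change 2.13, SE 0.58) but missed the threshold (edgeR adjusted p = 0.127).

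In this comparison 67 contigs passed in edgeR, 27 higher and 40 lower, and DESeq2 called 825 and limma-voom 391. A fit of these 2 sites alone called 11. Chosen after seeing the data, the component as a term called 956, and the exclusion of the 6 libraries lowest in digestive hydrolases called 0 (edgeR, 5202 at an unadjusted p under 0.05). Upper-quartile scaling called 25, 13 higher and 12 lower, and scaling by library totals alone called none (edgeR, 4181 at an unadjusted p under 0.05, against 5732 with TMM factors), with edgeR adjusted p of 0.352 for ACSL1, 0.343 for GNAS, 0.111 for contig_27540 and contig_19638, 0.212 for LOC106051311 and 0.275 for LOC105346775.3.3. No contig passed within lane 3 (edgeR, 6708 at an unadjusted p under 0.05), within lane 4 (6247) or against a log2 fold change beyond 1 (glmTreat, 78). The count was 198, 0, 1, 39, 4 and 8 without runoff individuals 49, 50, 53, 55, 56 and 63 (0 with 5026 contigs at an unadjusted p under 0.05 in edgeR). It was 2, 30, 3, 5 and 2 without reference individuals 20, 21, 29, 30 and 31. Without reference individual 31 the edgeR adjusted p was 0.0908 for ACSL1, GNAS, contig_27540, contig_19638 and LOC105346775.3.3, and without runoff individual 53 it was 0.0565 for LOC106051311.

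Genes of the DNA damage response were lower in runoff clams as a group (14 members, median log2 fold change -0.25, 14.3% positive; camera adjusted p = 0.0157, and adjusted p = 0.782 with an estimated correlation). No member passed in edgeR, DESeq2 or limma-voom, none did adjusted over the list alone, and 1, the excision repair factor XPA (-0.41, SE 0.16, edgeR adjusted p = 0.355), had an unadjusted p under 0.05. Contigs with a symbol leaned lower in every class of abundance in this comparison (medians -0.089 to -0.0966). Number-only contigs, most of those that camera compares a list with, leaned higher (0.0204 to 0.0795). How much of the list's shift goes with this was not tested. Names of apoptosis genes fixed before the data were examined were higher as a group (19 members, median 0.19, 94.7% positive; camera adjusted p = 0.0125, and adjusted p = 0.782 with an estimated correlation). Its members with the smallest p were inhibitors of apoptosis of the BIRC7 type, such as BIRC7.3.9 (0.63, SE 0.192, edgeR adjusted p = 0.184) and BIRC7.7.9 (0.55). None passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The wider list of 47 apoptosis genes was not called (camera adjusted p = 0.618). In the list of metabolism of foreign compounds (camera adjusted p = 0.723), none of 27 members passed over all contigs in edgeR, while DESeq2 called 2 higher and 1 lower and limma-voom 2 higher. Adjusted over the list alone, ADHX.2.2 (log2 fold change 2.54, adjusted p = 0.00574) and ADHX.1.2 (2.48, adjusted p = 0.00574) were higher and the cytochrome P450 CP2U1.2.2 (-0.33, adjusted p = 0.0196) lower. Camera adjusted p for ribosomal proteins and translation factors was 0.1 (median -0.10), and for muscle, cilia and germline markers it was 0.77, 0.954 and 0.723. The other lists had camera adjusted p of 0.117 or more.

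**Figure D3:**
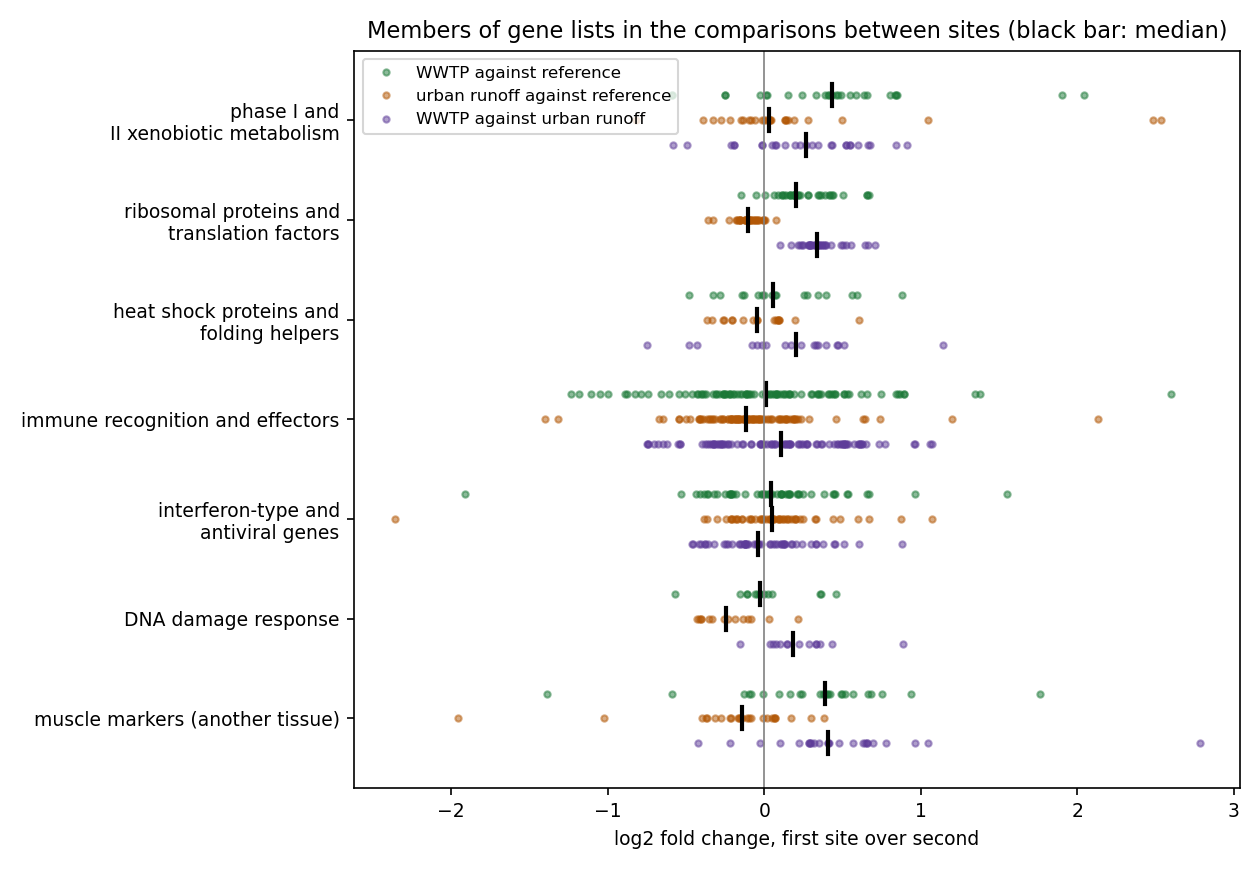
Log2 fold change of each member of 7 gene lists (points) and the list's median (black bar) in the comparisons between sites, first site over second. The ribosomal and translation list lies above 0 in WWTP clams against reference (median 0.21) and against runoff clams (median 0.34), and the DNA damage list below 0 in runoff against reference clams (median -0.25).

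The direct comparison of WWTP with urban runoff clams addresses whether the 2 effluents differ. sec61g rose to 122 ± 29.5 CPM from 67.7 ± 13.8 CPM in runoff clams (SD, n = 8; log2 fold change 0.85, SE 0.174, edgeR adjusted p = 0.0217). mgst1.1.2 rose to 31.1 ± 7.57 from 20.5 ± 3.14 CPM (0.60, SE 0.14, edgeR adjusted p = 0.0379), while mgst1.2.2 missed the threshold (0.66, SE 0.627, edgeR adjusted p = 0.747). BLMH, bleomycin hydrolase, a cysteine protease, was higher at 10.4 ± 2.02 against 5.86 ± 1.27 CPM (0.83, SE 0.17, edgeR adjusted p = 0.0217). The translation initiation factor IF4B was at 29.7 ± 5.6 against 18.8 ± 3.10 CPM (0.66, SE 0.126, edgeR adjusted p = 0.0176). The cyclophilin ppia, which helps proteins fold, was at 2.62 ± 1.26 against 1.19 ± 0.330 CPM (1.14, SE 0.247, edgeR adjusted p = 0.0271). KAD2, the adenylate kinase of the mitochondrial intermembrane space (0.68), ES1 (0.65), GAR1 (0.63) and ARF1.4.4, a small GTPase of the Golgi (0.61), also rose.

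LORF2.2.3, named for the second open reading frame of a LINE-1 element, was lower in WWTP clams, at 24.6 ± 3.97 against 35.8 ± 6.84 CPM (log2 fold change -0.55, SE 0.135, edgeR adjusted p = 0.0487). Chosen after their values were seen, the kinesin heavy chain KINH was at 22.3 against 15.7 CPM (0.50, edgeR adjusted p = 0.0418) and the NF-kappa-B subunit RELB at 1.14 against 1.59 CPM (-0.47, edgeR adjusted p = 0.0382). Without a symbol, Phum_PHUM345810 (1.15, edgeR adjusted p = 0.00576) and LOC105340223.1.2 (1.14) rose, and contig_03619 (-0.95) and contig_00638 (-0.90, edgeR adjusted p = 0.00185) fell. All 8 WWTP libraries lay beyond the runoff median for each gene named by the rule, except KAD2 with 7. For the contigs without a symbol this follows from the rule itself, which asks for no overlap.

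Of the contigs tested, 609 passed in edgeR, 443 higher and 166 lower in WWTP clams, with 26 symbols higher and 4 lower, and DESeq2 called 1968 and limma-voom 1633. The split turned with the scaling. Library totals alone called 541 contigs, 37 higher and 504 lower, and moved the median log2 fold change of all contigs to -0.20. Upper-quartile scaling called 253 higher and 170 lower. With totals alone edgeR adjusted p was 0.0376 for sec61g, 0.0718 for mgst1.1.2, 0.0554 for BLMH, 0.0547 for IF4B and 0.0773 for ppia. It was 0.0645 for KAD2, 0.229 for ES1, 0.105 for GAR1 and 0.0844 for ARF1.4.4. A fit of these 2 sites alone called 115 and, chosen after seeing the data, the component as a term 3027 and the exclusion of the 6 libraries lowest in digestive hydrolases 140. No contig passed within lane 3 (edgeR, 4411 at an unadjusted p under 0.05) or lane 4 (4362), and none passed against a log2 fold change beyond 1 (glmTreat, 170). The count was 223, 365, 295, 313 and 343 without runoff individuals 53, 56, 60, 62 and 63. It was 112, 1010, 330, 115 and 219 without WWTP individuals 38, 41, 42, 46 and 47. IF4B, Phum_PHUM345810, LOC105340223.1.2 and contig_00638 passed with any single library left out. The edgeR adjusted p rose to 0.114 for KAD2 and 0.0732 for ppia without WWTP individual 46, and to 0.104 for LORF2.2.3 without WWTP individual 38. Without individual 46 it was also 0.0563 for sec61g, 0.0569 for BLMH, 0.0592 for GAR1, 0.054 for ARF1.4.4 and 0.0923 for mgst1.1.2, and without individual 38 it was 0.0744 for ES1 and 0.0808 for contig_03619. With lane as a term KAD2 (edgeR adjusted p = 0.0576) and LORF2.2.3 (0.0514) missed the threshold, as Bscl2 did in WWTP against reference clams (0.0546).

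As groups, 8 of the 23 lists were called, all higher in WWTP than in runoff clams, and none kept an adjusted p under 0.05 with an estimated correlation. The fry test called 2 of them, heat shock proteins and folding helpers, and redox defence (adjusted p = 0.0245 each). It also called the foreign compound list in WWTP against reference clams (fry adjusted p = 0.0245), and none in runoff against reference clams. Named contigs leaned higher as a class in WWTP against runoff clams, with medians at 10 to 100 CPM of 0.147 for symbols (69.7% positive) and 0.142 for locus-named contigs. Number-only contigs, most of those that camera compares a list with, leaned lower at 1 to 10 CPM (-0.0602, 38.9% positive). How much of the list calls goes with this was not tested. Ribosomal proteins and translation factors were higher in each of 34 members (median log2 fold change 0.34; camera adjusted p = 2.44e-09, and adjusted p = 0.782 with an estimated correlation), with examples Rpl31.1.3 (0.66, SE 0.215, edgeR adjusted p = 0.133) and RL37A (0.65). Of the 34, 0 passed in edgeR, DESeq2 or limma-voom and 14 had an unadjusted p under 0.05. The estimated correlation between members was 0.791, against the preset 0.01. Contigs above 100 CPM rose as a class, with medians of 0.284 for symbols (84.3% positive), 0.333 for locus-named and 0.218 for number-only contigs. Whether the list differs from contigs of like abundance was not tested. The list of ribosomal names fixed before the data were examined gave camera adjusted p = 0.000102 (adjusted p = 0.782 with an estimated correlation). Of its 12 members 0 passed in edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05. Central energy metabolism had a positive log2 fold change in each of 14 members (median 0.28, camera adjusted p = 0.00205, and adjusted p = 0.782 with an estimated correlation), among them the pyruvate dehydrogenase subunit ODPB (0.42, edgeR adjusted p = 0.138). Of the 14, 0 passed in edgeR, limma-voom or adjusted over the list alone, 1 in DESeq2 and 5 at an unadjusted p under 0.05. Each of 10 nuclear respiratory chain genes had a positive log2 fold change (median 0.24, camera adjusted p = 0.0365, and adjusted p = 0.963 with an estimated correlation). Of these, 0 passed in edgeR or limma-voom, 1 in DESeq2 and 1 adjusted over the list alone. Heat shock proteins and folding helpers (18 members, median 0.20; camera adjusted p = 0.0291, and adjusted p = 0.368 with an estimated correlation) held 1 gene that rose, ppia. In this list 6 passed adjusted over the list alone, among them FKBP2 (0.46) and FKB1A (0.40), FK506-binding proteins that speed protein folding.

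Metabolism of foreign compounds was higher in WWTP than in runoff clams (27 members, median log2 fold change 0.27; camera adjusted p = 0.00878, and adjusted p = 0.629 with an estimated correlation), with mgst1.1.2 past the threshold. Adjusted over the list alone 3 passed, the others being aldh7a1 (0.31) and the monoamine oxidase MAOB (0.55). Lipid and sterol metabolism (15 members, median 0.25; camera adjusted p = 0.0157) and redox defence (16 members, median 0.15; camera adjusted p = 0.0404) were higher too, each with adjusted p = 0.782 with an estimated correlation. Examples are ACSL1 (0.36, edgeR adjusted p = 0.152) and the thioredoxin-like txndc12 (0.39, edgeR adjusted p = 0.222). With totals alone the camera adjusted p was 0.0657 for heat shock proteins and folding helpers, 0.124 for the nuclear respiratory chain and 0.0657 for redox defence. Immune recognition (0.0288) and digestive and lysosomal hydrolases (0.0216) passed with totals alone. Muscle markers had a median log2 fold change of 0.41 in the same comparison (camera adjusted p = 0.282, but 0.0102 with totals alone), beside 0.05 for cilia (0.94) and 0.10 for the germline (0.723). Lists not called had camera adjusted p of 0.451 for mitochondrial genome transcripts, 0.954 for immune recognition and for interferon-type genes, 0.282 for digestive and lysosomal hydrolases, 0.0704 for DNA damage response and 0.94 for mobile elements. Lists of heat shock and innate immunity names fixed before the data were examined were not called in any comparison, with camera adjusted p of at least 0.671 and 0.723. The 5 heat shock names leaned lower in WWTP than in runoff clams (median log2 fold change -0.0791, 20% positive). The call for heat shock proteins and folding helpers is therefore not shown for heat shock proteins themselves.

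Among all 3 sites 1172 contigs differed in a single edgeR test of any difference, with 9551 at an unadjusted p under 0.05, while DESeq2 called 3537 and limma-voom 3338. The count was 0 within lane 3 and 1 within lane 4. It was 383, 435, 619 and 741 without WWTP individuals 46, 38, 42 and 48, and 695, 742, 758 and 550 without reference individuals 20, 29, 30 and 31. Contigs called against the reference at both effluent sites were 12 higher and 10 lower, among them contig_27540 (higher at both) and LOC106051311 (lower at both). Of the 12 higher, 6 belong to 1 group of contigs that follow contig_27540 across libraries (r above 0.9), so they are not separate findings. Lists drawn independently would share 0.274 and 0.182. Both comparisons use the same 8 reference libraries. Simulated unchanged groups set against them in 12 draws called no contig in either comparison (edgeR), so they set no level for the number shared. Over all contigs the log2 fold changes of the 2 effluent sites correlated at 0.434, across contigs that are not independent replicates, against 0.487 ± 0.00719 in the simulated groups. Mixing the real libraries between sites gave a wider range, -0.0651 to 0.885, with 41 of 60 splits as large for the correlation and 29 of 60 for the covariance. The covariance was 0.0503 against 0.0543 and the share with the same sign 64.1% against 66.5%. With the reference libraries split into 4 and 4, 1 part for each comparison, the correlations were -0.0366 and 0.0305. No contig was called at both (edgeR; the parts called 8 and 0 contigs for WWTP and 0 and 0 for runoff). DESeq2 called 250 contigs at both sites and limma-voom 148, while library totals alone called none. The calls at both sites numbered 72, 0, 0, 12, 2 and 7 without runoff individuals 49, 50, 53, 55, 56 and 63, and 12 without WWTP individual 42 or 46. They numbered 1, 12, 14, 13, 43, 2, 3 and 1 without reference individuals 20, 21, 22, 23, 25, 29, 30 and 31.

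By abundance, none of the 100 most abundant contigs was called by edgeR in any comparison, where the shares called of all contigs (1.47%, 0.116% and 1.06%) predict few, and the difference was not tested. There were 172 higher and 34 lower in WWTP against reference clams in the class of 9000 contigs with the largest share called (2.29%). By kind of name, contigs with a number only gave 25 of the 27 higher calls in runoff clams and 3 of the 40 lower ones, while those with a locus number or tag gave 2 higher and 35 lower. In WWTP against runoff clams the number-only contigs gave 97 higher and 141 lower calls and the locus-named contigs 320 higher and 21 lower. No contig had at least 5 counts in at least 7 of 8 libraries of 1 site and 0 counts in at least 7 of 8 of another.

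Of 9 two-sided exact permutation tests of library measures none passed an adjusted p of 0.05. WWTP libraries detected 58013 ± 147 contigs (SD, n = 8) and reference libraries 58152 ± 41.3, a difference of -139 (exact p = 0.00793, Benjamini-Hochberg adjusted p = 0.0714). The exact p was 0.0286 in lane 3, the smallest that 4 against 4 can give, and 0.229 in lane 4. The difference was -903.2 for contigs with at least 10 counts (exact p = 0.0014, adjusted p = 0.0126 over a separate family of 9 tests with this and 1 other measure redefined), a measure that depends on depth. After every library was thinned to the smallest total it was -709 (exact p = 0.0793, adjusted p = 0.357, chosen after seeing the data), and the difference in contigs with any count was -142 (exact p = 0.0471, adjusted p = 0.248). The 100 most abundant contigs held 26.8% ± 2 of WWTP, 25.2% ± 1.60 of runoff and 25.2% ± 1.60 of reference counts (adjusted exact p of 0.198 or more).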

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

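Among 80 groups of 8 values, for the named genes and for library measures of each site, 9 held a library far from the others by Dixon's gap-to-range ratio. Chance flags about 1 group in 20, or 4 here, and all 9 were groups of named genes. Low values were ifi44_bis in reference individual 20 (0.339 CPM, next 1.13), LOC101857055 in WWTP individual 41 (7.84, next 13.1), LOC106051311 in reference individual 25 (6.23, next 7.41), ES1 in runoff individual 49 (1.34, next 2.05) and ARF1.4.4 in runoff individual 53 (28.3, next 35.9). High values were GAR1 in reference individual 25 (18.0 CPM, next 12.2), contig_33140 in reference individual 20 (3.33, next 1.39), ACSL1 in runoff individual 62 (3.19, next 2.26) and contig_03619 in runoff individual 49 (77.8, next 34.9). No biological explanation was tested for these.

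Of the tests below, only those of library depth and of the number-only share against the digestive component were predicted before the result was seen; all others were chosen only after the result was seen. Transcripts such as GUN and Amy.1.2 varied along 1 component within each site. Lane held 0.000918% of the component's variance, so lane does not account for it. The component still held 58.3% of the variance after every library was thinned to the smallest total, so unequal numbers of counts do not produce it. Library totals did fall along the component (r = -0.448, permutation p = 0.0284). Thinning cannot show why totals and component go together. A smaller share of gland in the tissue taken could account for the component, since muscle and cilia markers both increase along it. Their median slopes, 0.655 and 0.324 log2 CPM per SD, differed by 0.331, within the wider interquartile range of 0.485. An increase is not particular to markers of other tissues. All 34 ribosomal proteins and translation factors (median slope 0.117) and 19 of 21 cell division genes (0.184) increased too, by less. Against a smaller share of gland, 11 of 20 listed hydrolases also increase along the component, among them ctrl.L. A feeding or digestive state of the animal, for which the design holds no measure, stays open too.

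Contigs with a number only held 25.8% ± 1.5 of counts in WWTP, 28.2% ± 0.568 in runoff and 26.5% ± 1.33 in reference clams (SD, n = 8; two-sided exact p = 0.000932 for WWTP against runoff, Benjamini-Hochberg adjusted p = 0.00839, lanes exact p = 0.0857 and 0.0286; exact p = 0.00653 for runoff against reference, adjusted p = 0.0294, lanes exact p = 0.0286 and 0.2). Between WWTP and runoff clams the difference was -2.45 points, and -2.41 after regression on the digestive component (exact p = 0.000777 after it). Position on the component did not differ between these sites (exact permutation p = 0.44). The regression could therefore hardly change the difference and is no separate test of the component. Carry-over of genomic DNA could raise rare contigs, but the median of 1842 rare locus-named contigs differed by -0.143 log2 between runoff and reference (exact p = 0.0926), which cannot tell. No biological explanation was tested.

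A block of 14 contigs, among them ADHX.1.2 and ADHX.2.2 of the foreign compound list, followed contig_27540 (r above 0.9), with 10 called higher in WWTP and 7 in runoff against reference by edgeR; contig_27540 is itself called at both sites, so the choice of members largely fixes that direction. RNA of 1 other organism in constant proportions would keep the ratio to contig_27540, which differed between the effluent sites for 7 of 13 members; an organism whose own expression differs between sites stays open. The members carry 11 names, but 6 have a number only and so a name each, and this test cannot tell whether contigs share reads. With the digestive component as a term all 14 were called in runoff clams. Members were chosen to follow contig_27540, so these calls are 1 result. Among the members are contig_19638 and LOC108269088.3.3, whose rises given above are not separate from it. The log2 fold change of contig_27540 was 3.54 with the term and 3.71 without. Position on the component did not differ between runoff and reference clams (exact permutation p = 0.954). The term could therefore hardly lower the difference, and the number called is no separate test of the component. No biological explanation was tested.

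With libraries of the sites mixed in 60 splits including the true one, only the true split (1 of 60) gave as many edgeR calls for WWTP against reference (846, highest other 1), urban runoff against reference (67, highest other 5), WWTP against urban runoff (609, highest other 1) and the 3 sites (1172, highest other 3). For both effluent sites (22) it was 1 of 60 too, but splits that call almost nothing share nothing, so this sets no level for the overlap. At an unadjusted p under 0.05 other splits reached more contigs than the true one, in 4, 6 and 8 of 60 with the true one included (highest other 12881, 14824 and 12293 against 8376, 5732 and 7752), a count chosen after the result was seen. For gene lists, 37, 43 and 12 of 60 splits gave as many calls in the 3 comparisons, so the number of lists called could arise from differences between clams that have nothing to do with site.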

How the results depend on the processing

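The 37 named results were rerun with library totals alone, a lane term, the component term, DESeq2 and single libraries left out. Direction held in these, but the threshold often did not: 29 of 37 missed it in at least 1 of 24 leave-outs and 27 with library totals alone, while DESeq2 kept all 37. Simulated 1.5-fold changes were mostly missed (13.4% recovered in WWTP against reference). The cause was not tested for any move below, unless fewer libraries or a stricter limit is the change itself.

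Values are in the order WWTP against reference (846), urban runoff against reference (67), WWTP against urban runoff (609), any of 3 sites (1172) and both effluent sites (22). Library totals alone gave 165, 0, 541, 223 and 0, with 4181 contigs at an unadjusted p under 0.05 in edgeR for the 0. Upper-quartile scaling gave 522, 25, 423, 872 and 9. At least 2 CPM in at least 8 libraries gave 877, 106, 713, 1325 and 39. Lane 3 alone gave 0 in each, and lane 4 alone 1, 0, 0, 1 and 0. glmTreat gave 0 for each pair of sites and for both. Fits of 2 sites gave 516, 11 and 115. An adjusted p under 0.01 gave 66, 0, 23, 77 and 0. DESeq2 gave 2328, 825, 1968, 3537 and 250, and limma-voom 2606, 391, 1633, 3338 and 148. Leaving out single libraries gave 206 to 1342, 0 to 198, 112 to 1010, 383 to 1546 and 0 to 72.

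Chosen after seeing the data, the first principal component as a term gave 2649, 956, 3027, 4512 and 258, the hydrolase mean as a term 2754, 1082, 2437, 4447 and 338, and exclusion of the 6 libraries lowest in hydrolases 268, 0, 140, 322 and 0 (5202 at an unadjusted p under 0.05 in edgeR for the 0). Contigs with at least 10 counts differed by -903.2 between WWTP and reference (exact p = 0.0014, adjusted p = 0.0126), and by -708.6 after thinning (adjusted p = 0.357). Gene lists called by camera were 3, 2 and 8, 0 in each with an estimated correlation, 6, 5 and 10 with the component as a term, and 0 in each with the component as a term and an estimated correlation.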

Other observations

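With the digestive component as a term, chosen after seeing the data, edgeR called 70 symbols in WWTP against reference clams, 50 higher and 20 lower, and 2649 contigs in all. The names below were chosen after their values were seen. Higher were the interferon-induced ifi44l.3.3 (log2 fold change 1.29, SE 0.345, edgeR adjusted p = 0.0347), the interferon regulatory factor irf2 (0.72, adjusted p = 0.0486), the cytokine Mif (1.05, adjusted p = 0.0421), the deiodinase dio1 (1.32, adjusted p = 0.0275), the esterase EST2E.2.2 (0.86, adjusted p = 0.02) and the glutathione transferase mgst1.2.2 (0.52, adjusted p = 0.0247). None of these passed without the component term. There the edgeR adjusted p was 0.386 for ifi44l.3.3, 0.167 for irf2, 0.559 for Mif, 0.26 for dio1, 0.733 for EST2E.2.2 and 0.609 for mgst1.2.2. Mif (r = -0.964) and mgst1.2.2 (r = -0.976) follow the component closely. RELB, an NF-kappa-B subunit, was lower (-0.57, edgeR adjusted p = 0.00604). As a group, the 52 interferon-type and antiviral genes were not called in this fit (camera adjusted p = 0.987). In WWTP against runoff clams 97 symbols were higher and 8 lower, among them ODPB, of pyruvate dehydrogenase (0.50, edgeR adjusted p = 0.0117), the fumarase FUMH (0.33, adjusted p = 0.0209) and the malate dehydrogenase MDHM (0.32, adjusted p = 0.0283), and the folding helper FKBP2 (0.51, adjusted p = 0.00617). Without the component term FKBP2 missed the threshold (edgeR adjusted p = 0.0561). So did every member of the central energy metabolism list, ODPB among them. Muscle markers, of another tissue, were also higher in WWTP clams in this fit (camera adjusted p = 0.00958 against reference and 0.00322 against runoff, and adjusted p = 0.756 and 0.725 with an estimated correlation). The apoptosis names fixed before the data were examined were lower in WWTP than in runoff clams (camera adjusted p = 0.00772, and adjusted p = 0.71 with an estimated correlation).

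In runoff against reference clams the same fit called 4 symbols higher and 26 lower, of 956 contigs. Among those lower were GNAS (-0.55, SE 0.101, edgeR adjusted p = 0.0102), GNAQ (-0.46, adjusted p = 0.0172), GNAI (-0.31, adjusted p = 0.0389), CDC42 (-0.46, adjusted p = 0.00827), ARF6 (-0.35, adjusted p = 0.0305) and RAB2 (-0.48, adjusted p = 0.0427), as was the retinoid receptor RXR (-0.60, adjusted p = 0.0482). Of these only GNAS passed without the component term. There the edgeR adjusted p was 0.0524 for GNAQ, 0.321 for GNAI, 0.0586 for CDC42 and 0.12 for RXR. The names were chosen after their values were seen, from 26 that also include LETM1, KLF10 and PLXA1. No list of G proteins or small GTPases was tested. Without the term, contigs with a symbol leaned lower as a class in this comparison (29.1% to 38.6% positive by class of abundance).

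ADHX.1.2 averaged 45.5 ± 35.7 CPM in WWTP, 68.2 ± 53.6 in runoff and 12.2 ± 9.42 in reference clams (SD, n = 8), without passing over all contigs (edgeR adjusted p = 0.106 and 0.0921), and passed at both sites with the component as a term (2.28, edgeR adjusted p = 0.00185, and 2.51, adjusted p = 0.00326). It was chosen after its values were seen and belongs to the block around contig_27540. Library totals fell along the component (r = -0.448, permutation p = 0.0284, rho = -0.519, permutation p = 0.0105, the only one kept of 3 relations computed, since the other 2 used genes chosen because they followed each other or the component, r = -0.48 without 2 libraries, -0.36 and -0.569 within lanes).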
